A study of Mus musculus with 4 samples.

How the data were processed

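The deposited file analysed holds counts of unique molecular identifiers (UMIs) per gene and barcode, as whole numbers without normalisation, for replicate 1 of the all living cells group of Krt5-SmoM2 mouse esophagus. The libraries were made with droplet-based 3' chemistry, per the labels. The submitters' processing notes name bcl2fastq, Cell Ranger 3.1.0, STAR and the mm10 genome, without the role or order of each. The matrix was unfiltered and had 31057 features, 6794880 barcodes and 104569235 UMIs, with 1193386 barcodes holding a UMI. The other 3 samples, both of the EpCAM-high sort and replicate 2 of all living cells, were not analysed here. Of these only the gene and barcode names were read, and the 4 samples had 1 gene list in common. Of the 31053 Ensembl identifiers, 30934 were located in GENCODE mouse release 21, and the remaining 4 features were transgene sequences (YFP, eGFP, CRE and tdTomato).

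Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were taken as cells, which gave 6711. Scrublet as provided in scanpy, with an expected doublet rate of 6%, called 80 doublets (1.19%) at a score threshold of 0.314, and these were removed. The 6631 cells kept were normalised to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0 gave 30 clusters. Variable genes were drawn only from odd-numbered positions of the gene list and left out all 23 gene lists, mitochondrial and ribosomal protein genes and transgenes, so that genes on even positions and list genes took no part in clustering. Epithelial cells were clustered again in the same way into 18 sub-clusters. A cluster was named after the marker list with the highest mean log2 level among 30 lists, if that score was at least 1, at least 3 markers were detected in at least 10% of cells each, its 10 top genes did not include more markers of another class, and its median UMIs were not under the library's divided by 3 without an own marker among the top genes. Epithelial sub-clusters took the basal, suprabasal or columnar list with the highest score among lists with at least 3 detected markers, without a minimum score. Those with S phase or G2/M genes at 2 or more times the epithelial level were called cycling. Cells under 1000 UMIs, doublets and clusters without a name entered no comparison, except that the Epcam comparison took all epithelial cells.

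Counts were summed per class and given as CPM of the summed counts with exact Poisson 95% intervals. Shares of cells had exact binomial (Clopper-Pearson) intervals, and ratios of CPM the exact conditional binomial interval. A count of 0 was given an upper limit of 3 counts over the class, and a ratio against 0 counts is a lower bound from the same 3 counts. Log2 ratios had 10 CPM added to both sides. Each list median took the members with at least 50 UMIs over both sides, if there were at least 3, and its percentile was its rank among 10000 random lists of the same size matched on mean expression in 20 bins. The random lists were drawn from genes with at least 50 UMIs that were not mitochondrial and took no part in clustering. The variable genes used in clustering were thus absent from them, and percentiles against all genes were not computed. These percentiles describe this library and are not p-values. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, which left out 387 cells and kept 6244. Background was read from 1120826 barcodes with 1 to 100 UMIs (4303518 UMIs).

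The cell filters, clustering, marker lists, gene lists, comparisons and the rule for named genes were set before the data were examined. The thresholds for naming clusters were set afterwards. Among them, the order that puts detection before the score, and the counting of squamous differentiation genes as own genes of a sub-cluster, were set after the values of 2 sub-clusters concerned were seen. They foresaw a comparison of columnar-like with basal squamous cells, or of epithelial clusters by number if no columnar-like cluster was found. No such sub-cluster was found, so sub-clusters with at least 20 CPM of YFP were set against the others within the basal, suprabasal and cycling stages, a level chosen after the data were seen. Further comparisons were suprabasal against basal cells, Epcam-high against Epcam-zero epithelial cells, and levels in stromal classes. The rule for named genes took the 12 highest and 12 lowest log2 ratios with at least 50 UMIs, leaving out mitochondrial, ribosomal protein and unnamed genes, from even positions and without class markers (in the Epcam comparison all genes but Epcam), all HH targets and components, up to 4 members of each other list, and Epcam. Values of some genes that the rule names are not reported here. Class markers described in the comparisons, Mki67 and the genes described for the 4 cells with simple keratins were chosen after their values were seen.

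The gene lists were HH targets, HH components, sort marker (Epcam), foregut transcription factors, fetal growth genes, intestinal and gastric metaplasia genes, tight junction and polarity, hemidesmosome and basement membrane, desmosome, squamous differentiation, hair follicle progenitor genes, Wnt targets, Notch pathway, BMP and TGF-beta response, stromal niche factors, S phase, G2/M phase, dissociation stress, MHC class II, interferon response, cytokines and chemokines, mesenchymal transition, and epithelial identity.

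Alternatives covered other UMI minimums, mitochondrial limits, doublet treatment, resolutions and variable genes, the naming of sub-clusters, a mean over cells, subtraction of the empty-droplet profile, other thinning depths and draws, another constant, basal and cycling cells together, and the Epcam comparison without unnamed sub-clusters. The first thinning draw was changed so that each cell's draw no longer depended on the subset read. That change was made after values were seen, and 20 other draws were therefore added.

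The ratios and list percentiles were tested on simulated data built on the comparison of YFP-bearing with YFP-poor basal cells over 9883 genes. For 50 genes each with true ratios of 4, 2, 0.5 and 0.25 the median ratios found were 4.02, 1.99, 0.504 and 0.251, and 96.0%, 96.0%, 98.0% and 96.0% of intervals held the true value. For 9683 unchanged genes the share was 95.6%. A list of 12 genes raised 2-fold reached percentile 100. In a first draw of 40 unchanged lists the median percentile was 65.4, and in a later draw of 1000 lists it was 50.6, with 5.0% of lists under the 5th and 5.7% over the 95th percentile. Here the random lists came from all 9883 genes, those used in clustering included, and unchanged genes had counts from a common profile. These shares hold for that setting and do not calibrate the percentiles of the comparisons.

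Software was python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with random seed 0.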

Results

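The series comprised 4 droplet-based single-cell RNA libraries of esophagus from mice of the Krt5-SmoM2 genotype, 2 prepared from cells sorted for high EpCAM and 2 from all living cells. SmoM2 is a constitutively active mutant of Smo, the membrane protein that passes the Hedgehog (HH) signal into the cell, and Krt5 is a keratin gene of basal cells of stratified epithelia. Counts were analysed for replicate 1 of the all living cells group, and the other 3 libraries were not analysed here. No mouse without SmoM2 was included, so every comparison was made between cells of this library. There were no replicates, and no p-value was computed. Intervals are 95% intervals and cover counting error only.

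The library held 104569235 unique molecular identifiers (UMIs), of which 87043739 (83.2%) lay in 6631 cells kept after filtering. The kept cells had a median of 7857 UMIs and 2451 genes. Levels are given as CPM, a gene's share of the summed UMIs of a class on the usual scale, and every class is named after its marker genes, so that "fibroblast" stands for fibroblast-like.

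The first question was which cells the esophagus yielded. Epithelial cells made up 2354 of the 6631 cells (35.5%, 34.4 to 36.7) and fibroblasts 2297 (34.6%, 33.5 to 35.8). Immune cells numbered 715 (10.8%), namely 232 B or plasma cells, 203 T cells, 130 Langerhans cells, 116 macrophages or monocytes and 34 neutrophils. Endothelial cells numbered 574 (8.66%), of which 427 were blood and 147 lymphatic endothelial. Smaller classes were muscle satellite cells (208), mesothelial cells (114), Schwann or glial cells (83), pericytes (70) and smooth muscle cells (32), and 184 cells outside the epithelium were left unnamed. The cluster of muscle satellite cells had the protease genes Prss34 and Mcpt8 among its top genes beside Des and Myod1, so it may include cells of another type. Median depth ranged from 2530 UMIs in pericytes to 22970 UMIs in epithelial cells.

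**Figure D1:**
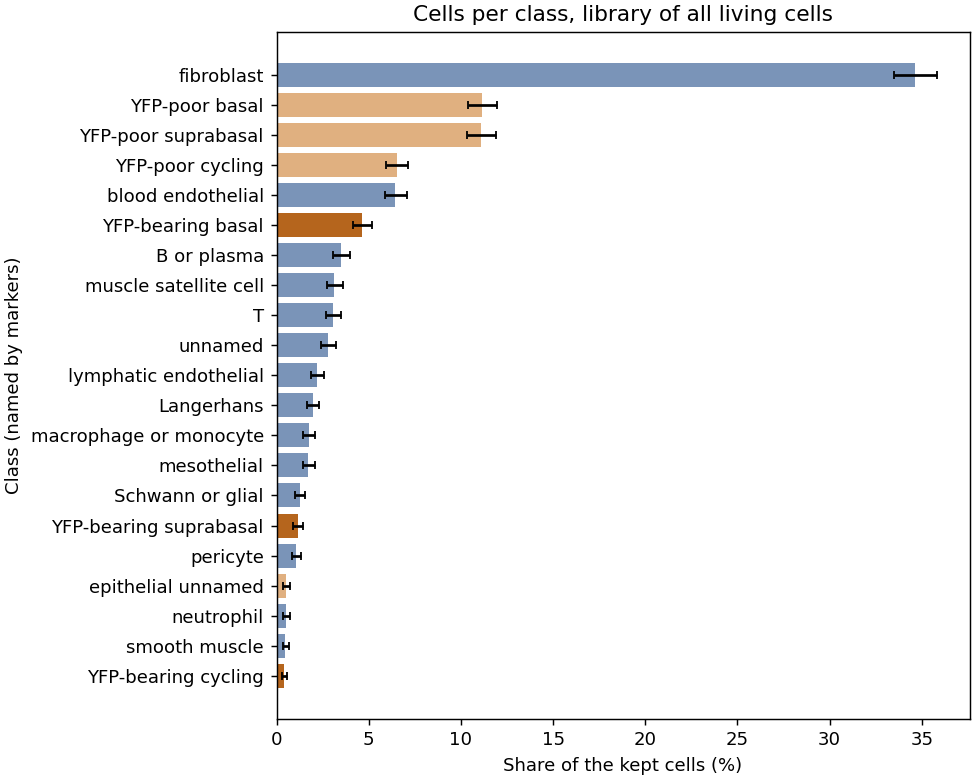
Share of the 6631 kept cells in each class, in percent, with exact binomial 95% intervals as error bars. Epithelial cells (35.5%) and fibroblasts (34.6%) together held most of the cells.

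The next question was which epithelial cells carried the transgene. A YFP transcript was quantified in the matrix, and YFP is fused to SmoM2 in a widely used conditional allele, although the labels do not name the allele. No epithelial sub-cluster met the criteria for a columnar-like name. The sub-cluster with most YFP-bearing cells had a mean columnar marker score of 1.30, above its basal score of 0.93, but only Krt20 (16.3% of its cells) of the columnar markers was detected in at least 10% of its cells, whereas 7 of 7 basal markers were. Of this sub-cluster's UMIs, 4 of its 307 cells held 135 of 138 for Krt8, 171 of 199 for Krt18, 127 of 146 for Krt19 and 87 of 119 for Krt7, so the part of the score that these genes give does not describe most of its cells. Krt20 was spread more widely, with 46 of its 276 UMIs in the 4 cells, and was 26.2-fold higher (18.5 to 38.3) in YFP-bearing than in YFP-poor basal cells and 45.1-fold higher (28.9 to 72.8) in suprabasal cells. The rule that put detection before the score was set after these values were seen. With this rule 0 columnar-like sub-clusters were found under each of 8 other clustering and filtering settings, so sub-clusters were divided by their YFP level. In 3 sub-clusters YFP stood at 31.0 (25.9 to 36.9) CPM in basal cells, 33.4 CPM in cycling cells and 32.7 (25.6 to 41.1) CPM in suprabasal cells. In the YFP-poor basal, cycling and suprabasal cells it stood at 0.28, 0.74 and 0.17 CPM. The YFP-bearing sub-clusters held 411 cells, 17.5% (16.0 to 19.1) of the epithelial cells, with 222 YFP UMIs in 165 cells, against 17 YFP UMIs in 16 of the 1908 YFP-poor cells. Of the remaining epithelial cells, 35 lay in 2 sub-clusters led by genes of stromal or immune cells and stayed unnamed.

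HH target genes were the readout of pathway activity. Ptch1, the HH receptor and a direct target of the pathway (ENSMUSG00000021466, mm10 chromosome 13, 63508328 to 63573598), stood at 518 (496 to 540) CPM in the 307 YFP-bearing basal cells and at 14.2 (12.3 to 16.3) CPM in the 740 YFP-poor basal cells, a 36.6-fold difference (31.6 to 42.4). Gli1, a transcription factor induced by HH signalling (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974), was 22.1-fold higher (15 to 33.7; 46.3 against 2.09 CPM). Hhip, a ligand-binding inhibitor and HH target in many tissues (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006), had 1 UMI in YFP-bearing basal cells and 0 in YFP-poor basal cells, where 0 counts allow up to 0.209 CPM. The median log2 ratio of the list of HH targets was 2.22, at percentile 100 among 10000 random lists of the same size matched on mean expression.

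Cells in cycle and suprabasal cells showed the same contrast. Ptch1 stood at 593 against 15.9 CPM in cycling cells, 37.2-fold apart (31.1 to 44.7), and at 190 (172 to 209) against 4.13 (3.35 to 5.02) CPM in suprabasal cells, 46.0-fold apart (36.9 to 57.8). Gli1 was 24.1-fold higher (15.4 to 37.9) in YFP-bearing cycling cells and 15.1-fold higher (8.49 to 27.4) in YFP-bearing suprabasal cells. The empty-droplet level was 33.0 CPM for Ptch1 and 6.27 CPM for Gli1, above both genes' levels in YFP-poor epithelial cells. It describes free RNA outside cells and sets no floor for levels in cells. Scaled on immune and stromal marker genes, the empty-droplet profile made up 1.18% of UMIs in YFP-poor basal, 1.19% in cycling and 0.71% in suprabasal cells.

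The share of cells with a Ptch1 UMI followed the levels. After thinning to 2000 UMIs per cell it was 59.7% (54.0 to 65.3) of YFP-bearing basal cells, with 4 cells left out for depth, against 2.71% (1.66 to 4.15) of YFP-poor basal cells, with 2 left out. It was 1.74% (0.36 to 5.01) in T cells, with 31 left out. Without thinning the shares were 97.1%, 18.1% and 4.93%, at median depths of 13099, 19935 and 4359 UMIs. Macrophages or monocytes, at a median of 8914 UMIs, had 0 of 106 thinned cells with a Ptch1 UMI, and 4.31% without thinning.

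Among the 9 measured pathway components the median log2 ratio of YFP-bearing over YFP-poor basal cells was 0.02, at percentile 30.8, with 5 higher and 4 lower. Gli2, the main activator of HH transcription, was 10.1-fold higher (6.54 to 16.2), and Sufu, a Gli-binding repressor, 2.30-fold higher (1.51 to 3.47). Smo transcripts, counted without separating the mutant from the native form (ENSMUSG00000001761, chromosome 6, 29735503 to 29761365), were 1.79-fold higher (1.55 to 2.05). Gli3, whose processed form represses targets, was 2.99 times lower (1.51 to 6.74). The co-receptor Gas1 was 1.39 times lower (1.16 to 1.66), and Boc, a further co-receptor, was 1.51 times lower (1.00 to 2.36). The ligand genes Shh and Ihh had 0 UMIs in both basal classes. In suprabasal cells Gli2 was again 10.7-fold higher (5.15 to 22.4), while Smo differed by 1.30-fold with an interval of 0.952 to 1.75.

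The main comparison set YFP-bearing against YFP-poor basal cells and asked which genes differed between them. The YFP-bearing cells formed 1 sub-cluster with a basal marker score of 0.93, and the YFP-poor ones several with scores from 0.48 to 1.5. S phase or G2/M genes stood at up to 1.34 times the epithelial level in the first and 0.6 to 1.0 times in the others. Median depth was 13099 against 19935 UMIs. Differences in this comparison may therefore mix basal state and cycle activity with YFP status. Krt17, a keratin of hair follicles and other appendages (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029), was 46.3-fold higher (44.9 to 47.7) and reached 14456 CPM against 312 CPM. Ces1f, a carboxylesterase gene, was 122-fold higher (100 to 152). Wif1, a secreted inhibitor of Wnt ligands, had 628 UMIs in YFP-bearing and 2 in YFP-poor basal cells, a ratio of 1075 (296 to 8895). Genes of extracellular matrix proteins were also among the highest ranked, with Fbln2 (fibulin) 59.6-fold higher (44.3 to 82.1), Tnc (tenascin) 13.9-fold (11.4 to 17.1) and Fndc1 13.0-fold (11 to 15.5). Further genes among the highest ranked were S100g (188-fold, 72.5 to 697), Epha7 (30.8-fold), Ank (27.4-fold), Csrp2 (19.8-fold), Alcam (15.9-fold) and Cldn1 (7.92-fold). The summed level of 6 fibroblast marker genes was 68.8 CPM in these cells and 20643 CPM in fibroblasts.

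Genes lower in YFP-bearing basal cells included Gpnmb, a membrane glycoprotein gene (26.2 times lower, 17.7 to 40.6), Dynap (29.2 times, 14.1 to 72.9) and H19, an imprinted noncoding RNA (23.5 times, 13.9 to 43.1). Hpgd, which encodes the enzyme that inactivates prostaglandins, was 13.7 times lower (10.48 to 18.1). Arhgdib (19.3 times), Kcnh1 (10.6 times), Ccdc3 (8.38 times), Car12 (6.61 times), Krt16 (4.84 times), Sult1d1 (4.68 times), the metallothionein gene Mt2 (4.34 times) and the apolipoprotein gene Apoe (3.50 times) completed the 12 lowest-ranked genes.

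Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129), the adhesion molecule used for the sort of the other group, was 2.92-fold higher (2.77 to 3.07) in YFP-bearing basal cells, at 652 (627 to 677) against 223 (216 to 231) CPM. In suprabasal cells it was 2.95-fold higher (2.79 to 3.13), and in cycling cells it stood at 1351 against 354 CPM. The non-epithelial class with the highest Epcam level was Langerhans cells at 1078 CPM, a class named in part by Epcam itself, and fibroblasts were at 6.56 CPM. Of tight junction and polarity genes, 11 of 12 measured were higher in YFP-bearing basal cells (median log2 ratio 0.53, percentile 100), among them Cldn1, Cldn7 (8.29-fold, 4.76 to 15), Cldn8 (6.57-fold) and Ocln (4.64-fold). The other epithelial identity genes were higher for 10 of 11 (median 0.30, percentile 99.4), with Spint1 1.96-fold and Rab25 1.5-fold higher.

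Hemidesmosome and basement membrane genes went both ways. Those on the list were higher for 9 of 10 (median 0.25, percentile 97.6), with the laminin genes Lama3 3.16-fold (2.71 to 3.68) and Lama5 2.19-fold higher and the integrin gene Itgb1 1.59-fold higher. The hemidesmosome genes among the basal class markers, which the list leaves out, were not higher, with Col17a1 1.44 times lower (1.35 to 1.54), Itgb4 1.19 times lower (1.08 to 1.31) and Itga6 at a ratio of 0.956 (0.884 to 1.03). Desmosome genes were higher for 7 of 9 (median 0.29, percentile 99.0), led by Dsc2 at 2.75-fold (2.40 to 3.16). Listed squamous differentiation genes were higher for 8 of 11 (median 0.27, percentile 98.3), with Sprr1a 3.37-fold (3.0 to 3.79) and Grhl3 2.55-fold higher and Ovol1 1.44 times lower. The suprabasal class markers, which the list leaves out, were divided. Krt4 was 7.24 times lower (6.46 to 8.14), Krt13 3.18 times (3.1 to 3.27) and Tgm3 2.77 times lower (2.39 to 3.21), whereas Krt6a was 3.0-fold (2.91 to 3.1), Lor 2.35-fold and Krtdap and Sbsn both 1.88-fold higher. Mesenchymal transition genes had 3 measured members, of which Zeb2 was 12.6-fold (7.67 to 21.4) and Vim 1.75-fold higher and Snai2 1.25 times lower (median 0.56, percentile 98.5).

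Genes of hair follicle progenitors were higher for 8 of 9 measured (median 0.86, percentile 100). Besides Krt17 and Alcam, the stem cell receptor gene Lgr5 had 162 against 4 UMIs, a ratio of 139 (53.1 to 515), and the transcription factor gene Runx1 was 3.31-fold higher (2.91 to 3.77). Wnt targets were higher for 6 of 8 (median 0.83, percentile 100). Of these, Lgr6 had 50 UMIs against 0, at least 57.1-fold higher against a floor of 3 counts over the class, and Znrf3, a Wnt receptor ligase, was 3.03-fold higher (2.39 to 3.83). BMP and TGF-beta response genes were higher for 6 of 8 (median 0.54, percentile 100), with Id1 2.57-fold (2.34 to 2.82), Bmp7 2.83-fold and Id3 2.18-fold higher and Id2 2.33 times lower. Notch pathway genes went both ways (3 of 7 higher, median -0.09, percentile 7.29), with the target Hes1 2.04-fold and Notch2 2.99-fold higher and the ligand Dll1 1.94 times lower. Of stromal niche factors only 2 were measured, Wnt5a at 3.04-fold higher (2.08 to 4.43) and Bmp4 at 1.12 times lower (0.828 to 1.53).

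Foregut transcription factors were divided, with 3 of 6 higher (median 0.13, percentile 80.2). Sox9, active in foregut progenitors and columnar epithelia, was 2.63-fold higher (2.29 to 3.03), and Sox2, a regulator of squamous foregut identity, was 2.16-fold higher (1.97 to 2.37). Pitx1 was 1.64 times lower (1.53 to 1.77) and Foxa1 1.56 times lower (1.19 to 2.09). Among fetal growth genes 3 of 5 were higher (median 0.14, percentile 67.3), with Sox4 4.16-fold higher (3.84 to 4.50), Igf2bp3 3.24 times lower and H19 lower as given above. Of the 17 intestinal and gastric metaplasia genes, 0 reached 50 UMIs over both basal classes.

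The direction of cell cycle genes depended on the cells compared. Cycling sub-clusters held 27 of the 411 YFP-bearing cells (6.6%, 4.4 to 9.4) and 432 of the 1908 YFP-poor cells (22.6%, 20.8 to 24.6) and were left out of the basal comparison. Clustering of all cells had given a cluster of 48 cells with Cenpf, Top2a, Wif1 and Ptch1 among its top genes. The share of YFP-bearing cells in cycle may therefore depend on the clustering. Among the basal cells that remained, S phase genes were higher for 16 of 17 (median 0.56, percentile 100), with Tyms 2.15-fold (1.79 to 2.57) and Rrm2 2.46-fold higher. Clspn was 3.92-fold higher, but its log2 ratio was -0.11 with a minimum of 500 UMIs per cell. G2/M genes were higher for 11 of 13 (median 0.40, percentile 99.9), with Top2a 3.80-fold (3.08 to 4.68) and Cdk1 3.76-fold higher. Mki67 stood at 31.0 against 32.2 CPM, and after thinning 6.27% and 6.10% of cells had a UMI of it. With basal and cycling cells pooled, an alternative chosen after these values were seen, S phase genes were lower for 13 of 19 (median -0.27, percentile 0) and G2/M genes for 20 of 20 (median -0.54, percentile 0) in YFP-bearing cells, and the Mki67 ratio was 0.54 (0.49 to 0.60).

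Cytokine and chemokine genes were lower for 5 of 7 (median -0.28, percentile 0.13), led by Cxcl1 at 2.47 times (2.16 to 2.84) and the alarmin Tslp at 4.87 times lower. MHC class II genes were higher for 4 of 4 (median 0.30, percentile 93.5), with H2-Ab1 2.76-fold higher (2.37 to 3.21). The empty-droplet profile was estimated at 1.58% of UMIs in YFP-bearing and 1.18% in YFP-poor basal cells, and its part in this median was not tested. Interferon response genes were higher for 3 of 6 (median 0.16, percentile 81.9), and Cxcl10 was 1.80 times lower. Dissociation stress genes were higher for 12 of 16 (median 0.25, percentile 99.9), with Ier3 1.84-fold higher and Fosb 1.47 times lower. More than 10% mitochondrial UMIs were found in 13.4% (9.8 to 17.7) of YFP-bearing and 8.1% (6.2 to 10.3) of YFP-poor basal cells, at medians of 3.98% and 4.0%. Without these cells the median of the stress genes was 0.24 (percentile 99.9).

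**Figure D2:**
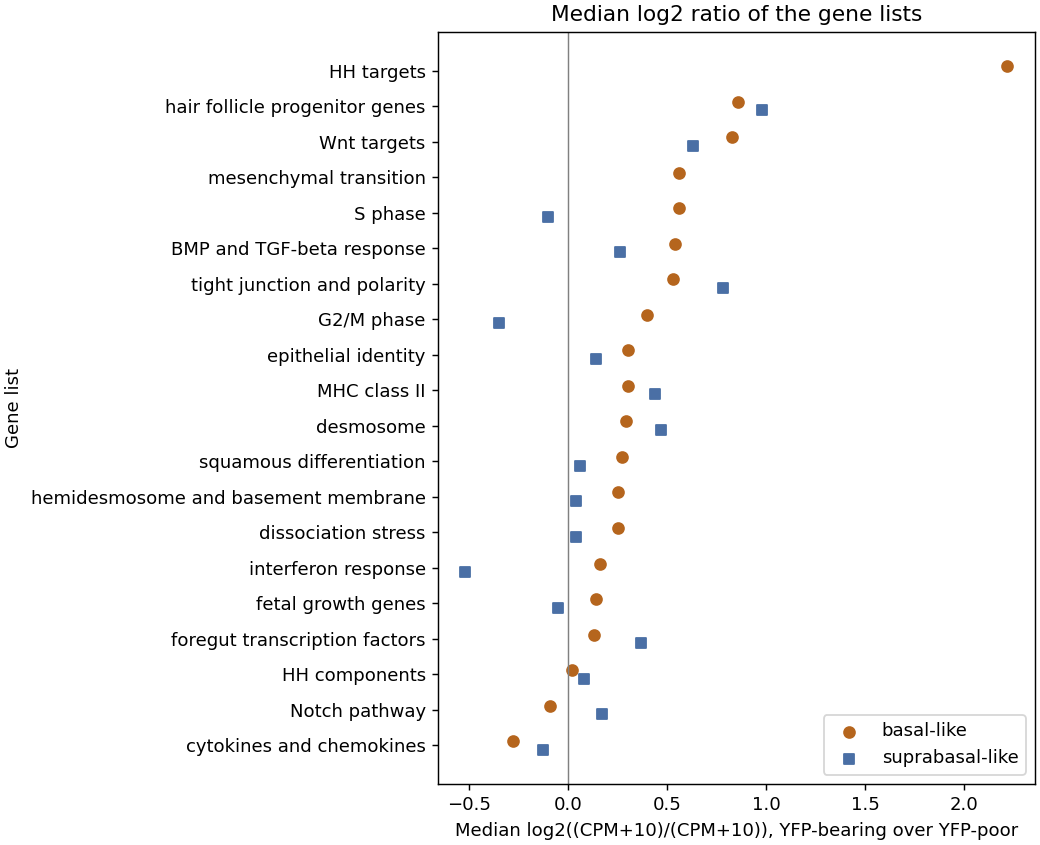
Median log2 ratio of YFP-bearing over YFP-poor cells for each gene list, for basal and suprabasal cells, over the members with at least 50 UMIs. Each value is a median over genes of this library and carries no error bar, and HH targets have the highest median in basal cells at 2.22.

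In suprabasal cells, which lie above the basal layer and differentiate, 77 YFP-bearing cells were set against 736 YFP-poor cells. The YFP-bearing cells formed 1 sub-cluster with a suprabasal marker score of 1.58, and the YFP-poor ones 6 with scores from 0.29 to 2.85, the highest in a sub-cluster led by Lor, Cnfn and Crabp2. Differences in this comparison therefore mix maturation stage with YFP status. Krt17 stood at 21351 against 150 CPM (142-fold, 137 to 147). Krt75, a keratin of the hair follicle, had 288 UMIs against 0, at least 1031-fold higher against the floor of 3 counts. S100g, a calcium-binding protein gene, was 420-fold higher (260 to 725), and Ces1f 53.3-fold (47.5 to 59.9). Alcam (40.6-fold), Lce3a (28.9-fold), Ldhb (27.9-fold), Csrp2 (27.5-fold), Fbln1 (11.6-fold), Rbp7 (11.6-fold), Hopx (9.65-fold) and Glul (8.52-fold) followed.

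Of the 12 lowest-ranked genes in YFP-bearing suprabasal cells, Chil4, a chitinase-like protein gene, was 54.9 times lower (35.2 to 91.3) at 8.50 against 467 CPM, and Dynap 51.7 times lower (28.1 to 108). Sprr2i was 20.4 times lower (13.0 to 33.9), Crabp2, a retinoic acid-binding protein gene, 16.8 times lower (8.82 to 36.8), and the protease inhibitor gene Slpi 6.24 times lower (5.70 to 6.86). Gpnmb (19.2 times), Car12 (15.7 times), Apoe (8.50 times), Ddit4 (8.28 times), Mt2 (6.60 times), Il1f9 (6.23 times) and Sprr2f (4.09 times) were the others. Of the YFP-poor suprabasal cells, 136 formed a sub-cluster led by Sprr2f and Crct1 whose top genes also included S100a8 and S100a9, which are neutrophil markers, and it kept its name by a rule set after it was seen. Without it the log2 ratio was -3.88 for Chil4 (-4.69 with it), -1.23 for Sprr2f (-1.95), -1.43 for Sprr2h (-2.06) and -0.65 for Crct1 (-1.34). Members of the Sprr2, Lce3, Chil, Ces1 and Mt families have near-identical relatives, and the split of their counts within a family is uncertain.

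Tight junction and polarity genes were higher for 14 of 14 measured in YFP-bearing suprabasal cells (median 0.78, percentile 100), with Cldn1 5.11-fold (4.72 to 5.53), Marveld3 5.05-fold and Ocln 4.24-fold higher. Desmosome genes were higher for 7 of 9 (median 0.47, percentile 99.9), with Dsc2 2.21-fold and Dsp 2.07-fold higher, and hair follicle progenitor genes for 6 of 8 (median 0.98, percentile 100). Foregut transcription factors were higher for 4 of 6 (median 0.37, percentile 98.8), with Sox9 2.75-fold (2.30 to 3.26) and Sox21 2.60-fold higher. Squamous differentiation genes were split, 7 of 12 higher (median 0.06, percentile 77.2), with Sprr1a 3.0-fold higher (2.92 to 3.07), Sprr2h 6.39 times lower and Crct1 2.55 times lower (2.42 to 2.69). Of the suprabasal class markers, Krt4 was 21.5 times lower (20.2 to 22.8) at 500 against 10734 CPM, Krt13 2.11 times and Lor 1.98 times lower, whereas Krt6a was 10.6-fold (10.4 to 10.8), Sbsn 1.65-fold (1.59 to 1.70) and Cnfn 1.49-fold higher (1.43 to 1.56). Interferon response genes were lower for 4 of 5 (median -0.52, percentile 0.07), with Ifitm3 2.48 times lower (2.24 to 2.75). The alarmin gene Il1a was 13.5-fold higher (10.48 to 17.5), and the chemokine genes Cxcl1 and Ccl20 were 2.23 and 2.06 times lower. G2/M genes were lower for 9 of 11 (median -0.35, percentile 0.01), and Mki67 had 1 UMI in these 77 cells.

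**Figure D3:**
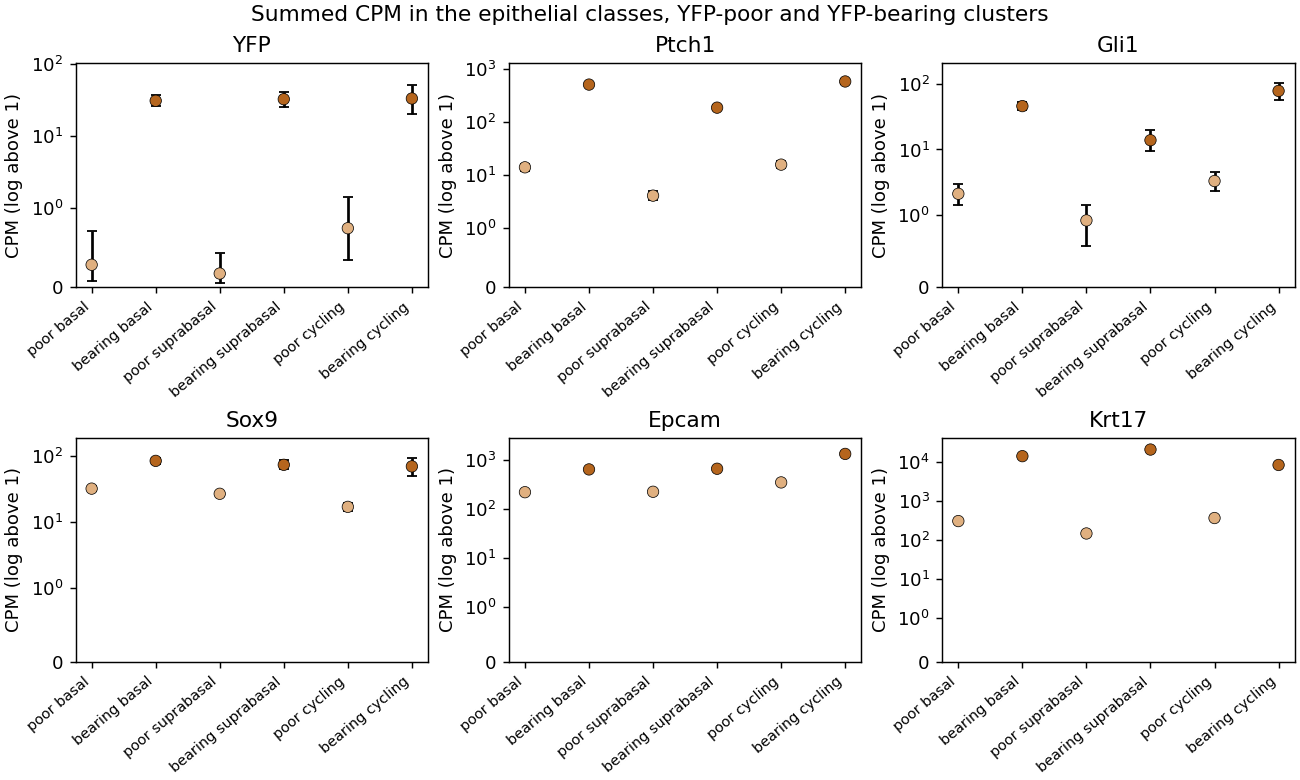
Levels of selected genes in the YFP-bearing and YFP-poor basal, cycling and suprabasal cells, in CPM of summed UMIs on an axis that is logarithmic above 1 CPM and linear below, with exact Poisson 95% intervals as error bars. Krt17 stands at 14456 and 21351 CPM in YFP-bearing basal and suprabasal cells and at 312 and 150 CPM in the YFP-poor ones.

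The cycling cells compared 27 YFP-bearing with 432 YFP-poor cells. Wif1 was 225-fold higher (124 to 447), Ank 54.0-fold (34.1 to 87.7), Fbln2 46.1-fold (34.3 to 62.5) and Ces1f 41.0-fold (34.2 to 49.3) in the YFP-bearing cells. Chil4 had 0 UMIs against 1518, at least 23.6-fold lower. S phase genes were lower for 17 of 19 (median -1.03, percentile 0) and G2/M genes higher for 20 of 20 (median 0.96, percentile 100). The YFP-bearing cycling cells formed 1 sub-cluster, with Cenpf, Aspm and Ube2c among its top genes, and the YFP-poor ones 3, led by histone, G2/M and Mcm genes. Differences in this comparison therefore mix cycle phase with YFP status.

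Suprabasal cells were then compared with basal cells within the YFP-poor epithelium to describe its squamous maturation. Crct1, a cornification gene, was 86.3-fold higher (76.6 to 97.7) in suprabasal cells at 1626 against 18.8 CPM, and Sprr1b 74.6-fold (63.4 to 88.4), Sprr1a 30.1-fold and Slpi 48.6-fold (43.9 to 53.8). Without the 136 cells of the sub-cluster with S100a8 and S100a9, the log2 ratio of Crct1 was 5.14 in place of 5.83. The claudin gene Cldn4 was 19.6-fold higher (16.5 to 23.4). Wnt10a, a Wnt ligand gene, was 8.68 times lower (7.94 to 9.50), the matrix gene Efemp1 14.2 times, the Notch ligand Jag2 28.5 times (22.1 to 37.5), Itga3 17.4 times and Snai2 16.4 times. Squamous differentiation genes were higher for 12 of 12 (median 1.52, percentile 100) and desmosome genes for 8 of 9 (median 1.01, percentile 100). Hemidesmosome and basement membrane genes were lower for 10 of 10 (median -1.33, percentile 0), HH components for 9 of 9 (median -0.60, percentile 0) and S phase genes for 16 of 17 (median -0.93, percentile 0). Suprabasal cells were named by markers of squamous maturation such as Krt4 and Lor, and basal cells by markers that include the hemidesmosome gene Col17a1. Squamous differentiation genes also counted as own genes in the naming. The directions of the squamous differentiation and hemidesmosome lists therefore follow in part from the naming. Krt17 was 2.08 times lower by summed counts but had a log2 ratio of 0.28 as a mean over cells.

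In YFP-bearing cells suprabasal cells were compared with basal cells in the same way, and the difference between the 2 steps was not tested. Squamous differentiation genes were higher for 11 of 11 (median 1.65, percentile 100), with Sprr1a 26.8-fold (24.6 to 29.2) and Crct1 38.2-fold higher (30.01 to 49.2), and hemidesmosome genes were lower for 10 of 10 (median -1.92, percentile 0). Both directions likewise follow in part from the markers that named the stages. Ly6g6c (187-fold, 117 to 323), Spink5, a protease inhibitor gene (53.2-fold), Calml3 (37.8-fold), Hopx (36.8-fold) and Krt16 (32.3-fold) were among the genes ranked highest. Wnt10a had 2 UMIs in suprabasal and 450 in basal cells, 120 times lower (33.0 to 994), and Igfbp5 (23.9 times), Tnc (18.6 times), Fbln2 (8.06 times) and Ifitm3 (7.24 times) were lower as well. Wnt targets were lower for 5 of 5 (median -1.03, percentile 0.03), and in YFP-poor cells for 4 of 4 (median -0.26, percentile 25.5). Cytokine and chemokine genes were higher for 5 of 6 (median 1.42, percentile 100), against 5 of 11 in YFP-poor cells (median -0.02, percentile 85.5). The measured members of the list differ between the 2 steps.

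HH targets were lower in suprabasal than in basal cells among YFP-bearing cells. Ptch1 fell to 190 from 518 CPM (2.73 times lower, 2.46 to 3.03), and Gli1 was 3.34 times lower (2.28 to 5.05). The median of the list was -1.40 (percentile 0.03). These levels are shares of UMIs, and median depth was 27433 UMIs in the suprabasal and 13099 in the basal cells, so a fall per cell was not shown. Over the same step the YFP level had a ratio of 1.05 (0.78 to 1.41), but both sub-clusters had been chosen for at least 20 CPM of YFP, which limits how far this ratio can fall. Among cells with a YFP UMI, 44 suprabasal and 107 basal, Ptch1 stood at 175 (154 to 198) and 465 (432 to 500) CPM, from 255 and 736 UMIs. In YFP-poor cells Ptch1 was 3.43 times lower (2.69 to 4.41) in suprabasal cells. The levels on both sides lay below that of empty droplets, which sets no floor for cells.

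Because the other group was sorted for high EpCAM, Epcam-high and Epcam-zero epithelial cells were compared within this library. The 2322 epithelial cells with enough depth were thinned to 2000 UMIs, and 32 were left out. The top 25% of cells with Epcam UMIs, ties included, had at least 2 of them and comprised 382 cells, of which 223 stood at exactly 2, against 1335 cells with 0 and 605 in between. Cells of unnamed sub-clusters were included, 1 on the Epcam-high and 27 on the Epcam-zero side. This is a range of 1 gene's RNA level, not a cell type, and its relation to the sort was not tested. Epcam-zero means no Epcam UMI among the 2000 kept by thinning, and such cells can hold Epcam UMIs at full depth. The Epcam-zero side included 94 YFP-bearing basal cells, a class with a higher Epcam level than YFP-poor basal cells. Median depth was 20064 UMIs on the Epcam-high side and 24199 on the Epcam-zero side.

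YFP-bearing cells made up 43.5% (38.4 to 48.6) of Epcam-high and 8.76% (7.30 to 10.4) of Epcam-zero cells. Ptch1 was 4.46-fold higher (4.12 to 4.83) in Epcam-high cells, Krt17 4.89-fold (4.83 to 4.95), Ces1f 5.48-fold, Wif1 8.49-fold and S100g 19.4-fold (15.9 to 23.8). Krt4, a suprabasal keratin, was 2.64 times lower (2.60 to 2.68), and Crabp2 and Slpi were lower at log2 ratios of -1.34 and -1.32. G2/M genes were higher for 20 of 20 (median 1.10, percentile 100), led by Cenpf at 3.85-fold and Cenpa at 3.53-fold, while S phase genes were lower for 17 of 19 (median -0.17, percentile 0). Tight junction genes were higher for 15 of 15 (median 0.32, percentile 100) and hemidesmosome genes for 10 of 10 (median 0.34, percentile 100).

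Within YFP-poor cells alone, G2/M genes stayed higher for 20 of 20 (median 1.23, percentile 100). Cycling cells were 80 of 215 on the Epcam-high and 236 of 1191 on the Epcam-zero side. Ptch1 was 2.60-fold higher (2.07 to 3.24) at a log2 ratio of 0.78, and Krt17 was 3.08-fold higher (2.95 to 3.21). Of all YFP-poor cells, 16 had a YFP UMI and held 64 Ptch1 and 1557 Krt17 UMIs, against 432 and 11084 in the 1892 without. Their Epcam levels were 489 and 255 CPM. Only 34.9% of YFP-bearing basal cells had a YFP UMI, so further such cells may go unseen. The 2 ratios therefore do not separate Epcam from YFP status. The log2 ratio of Krt10, 1.66 in all cells, was -0.13 in YFP-poor cells. Tight junction genes were higher there for 10 of 15 (median 0.07, percentile 91.7) and hemidesmosome genes for 9 of 10 (median 0.13, percentile 96.1). The side a cell falls on depends on the random thinning. In 20 other draws the Ptch1 log2 ratio ranged from 1.36 to 1.99 in all cells and from 0.13 to 0.80 in YFP-poor cells, that of Krt17 in YFP-poor cells from 0.49 to 1.97, and that of S100g in all cells from 0.56 to 2.85. In all cells the log2 ratio of Krt4 ranged from -1.55 to -0.86, that of Crabp2 from -1.63 to -0.35 and that of Slpi from -1.12 to -0.05, a range that does not hold the value given above. The median of G2/M genes ranged from 0.67 to 1.13 in all cells.

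The last comparison concerned HH and niche genes in the stroma. Hhip was found mainly in fibroblasts, at 26.0 (23.5 to 28.7) CPM with 404 of the 417 UMIs in kept cells. It stood at 42.6 (37.8 to 47.8) and 22.9 (18.1 to 28.7) CPM in the largest 2 of 5 fibroblast clusters and at 2.48 and 5.20 CPM in the smallest 2. Fibroblast Gli1 was 7.72 (6.40 to 9.23) CPM and Ptch1 18.5 (16.5 to 20.8) CPM, the first close to and the second below the empty-droplet levels given above. Those levels describe free RNA and set no floor for cells. Ptch1 stood at 60.3 (35.1 to 96.5) CPM in Schwann or glial cells and 51.7 (35.1 to 73.4) CPM in lymphatic endothelial cells. Dhh, a HH ligand gene, had 13 UMIs in Schwann or glial cells (46.1 CPM, 24.5 to 78.8) and 41 in blood endothelial cells (14.1 CPM, 10.2 to 19.2), whereas Shh and Ihh had 3 and 10 UMIs in all kept cells.

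The co-receptor gene Gas1 stood at 198 CPM in fibroblasts and 626 (563 to 693) CPM in mesothelial cells, Cdon at 92.8 CPM in mesothelial cells and Boc at 62.9 CPM in fibroblasts. Of stromal niche factors, fibroblasts had Igf1 at 249 (241 to 257) CPM, the HH-responsive transcription factor gene Foxf1 at 120 (114 to 125) CPM, the epithelial growth factor gene Fgf7 at 76.2 CPM and Bmp4 at 57.0 CPM. Foxf1 was 153 (111 to 205) CPM in smooth muscle cells. Grem1, a BMP antagonist gene, was found at 80.9 (65.7 to 98.6) CPM in 1 fibroblast cluster, where 19 of 231 cells (8.23%, 5.02 to 12.6) held its 98 UMIs and 6.07% of cells had one after thinning, and had 0 UMIs in 3 of the other fibroblast clusters.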

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

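The level of YFP in barcodes outside the comparisons was looked at against the limit that a count of 0 allows, and no explanation was tested for it. The groups of barcodes were chosen after the data were seen. Empty droplets held 57 YFP UMIs, a level of 13.2 (10.0 to 17.2) CPM. Barcodes with at least 200 UMIs that failed the cell filters numbered 6520 and held 14 YFP UMIs (3.8 CPM, 2.1 to 6.4), with Ptch1 at 82.6 CPM. The 35 epithelial cells left unnamed held 10 YFP UMIs (8.3 CPM, 4.0 to 15.2), with Ptch1 at 49.6 CPM. The 80 cells called doublets held 5 YFP UMIs (2.9 CPM, 0.9 to 6.7), with Ptch1 at 50.4 CPM. All 4 counts were above the 3 UMIs that a count of 0 allows, a limit that any group with at least 4 UMIs passes, and for doublets the interval reached below it. All 4 levels lay between those of the YFP-poor and the YFP-bearing classes. The eGFP, CRE and tdTomato sequences had 0 UMIs in empty droplets and in kept cells.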

How the results depend on the processing

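The naming of sub-clusters without squamous differentiation genes, the restrictions to cells with a YFP UMI and to YFP-poor clusters, basal and cycling cells together, the mitochondrial limit with clusters kept, the Epcam comparison without unnamed sub-clusters, the 20 other thinning draws, a YFP level of 10 CPM and the totals without the 100 most abundant genes were tests chosen only after the results were seen. Of the recomputed values that answer a comparison, 121 stayed within their counting interval and 14 did not, and none of these changed direction. Some of the 121 could not move, because a YFP level of 10 CPM left every sub-cluster's name unchanged. The epithelial share (35.5%) and the Ptch1 log2 ratio of the Epcam comparison (1.88) were likewise unchanged at resolutions 0.5 and 2.0. The count therefore overstates how often the results were put to a test. The number of named genes at least 2-fold apart that kept their direction stayed within 1.5 times its value in all 69 repeats, and 3 single values of such genes turned. These counts leave out gene values in the 20 other thinning draws. There Sprr2j-ps and Sprr2i, at log2 ratios of -1.56 and -1.24 in the Epcam comparison, each kept their direction in 19 draws. With basal and cycling cells together, 2 list medians of the basal comparison turned, from 0.56 to -0.27 for S phase and from 0.40 to -0.54 for G2/M genes. Naming without squamous differentiation genes left 136 YFP-poor suprabasal cells unnamed and gave Ptch1 log2 ratios of 3.80 between suprabasal classes and -1.40 between YFP-bearing stages. The Ptch1 log2 ratio between basal classes was 4.45 and ranged from 4.30 to 5.10 over the alternatives run, that of Gli1 was 2.22 (1.89 to 3.94), and fibroblast Hhip was 26.0 CPM (25.4 to 26.4). With a minimum of 2500 UMIs epithelial cells were 38.1% and fibroblasts 35.8% of cells, and with a minimum of 500 UMIs the Clspn log2 ratio turned to -0.11. A mitochondrial limit of 10% with new clustering gave 14.8% YFP-bearing cells, 322 in place of 411. Above that limit were 50 of the 411 YFP-bearing cells (12.2%, 9.2 to 15.7) and 125 of the 1908 YFP-poor cells (6.6%, 5.5 to 7.8), and without them, with clusters kept, the log2 ratios of basal cells were 4.39 for Ptch1, 2.19 for Gli1 and 1.46 for Epcam. The Epcam log2 ratio of basal cells, 1.5, was 1.64 with doublets kept, 1.60 as a mean over cells and 1.68 for cells with a YFP UMI. The Ptch1 stage ratio, -1.40, was -1.36 in cells with a YFP UMI and -1.58 at resolution 0.5, and Krt17 between stages of YFP-poor cells turned to 0.28 as a mean over cells. In the Epcam comparison the Ptch1 log2 ratio, 1.88, was 1.09 with thinning to 1000 UMIs, 0.78 in YFP-poor clusters, 1.87 without unnamed sub-clusters and 1.76 as the median of 20 other draws, and Krt10 turned to -0.13 in YFP-poor clusters. For these values the cause was not tested. A constant of 1 CPM shrinks ratios less by construction and gave 5.10 for Ptch1 and 3.94 for Gli1 in basal and 5.22 for Ptch1 in suprabasal cells, and leaving out thinning keeps more UMIs per cell and gave 97.1% of YFP-bearing basal cells with a Ptch1 UMI. A YFP level of 10 CPM changed the naming of no sub-cluster. No paired analysis was possible because 1 library was analysed. Depth limits YFP in single cells: 107 of 307 YFP-bearing basal cells (34.9%) had a YFP UMI, against 102 (33.2%) expected from a common rate at each cell's depth.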

Other observations

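The tests of YFP-poor cells mixed into the suprabasal cluster and of doublets with mesothelial cells were chosen only after the results were seen, as were the splits of cells by YFP UMI. Immune and stromal classes differed in their cytokine genes. The neutrophil attractant gene Cxcl2 stood at 30200 (29883 to 30520) CPM in macrophages or monocytes and 14830 CPM in neutrophils, and Il1b at 3622 and 4406 CPM. Among stromal classes, Cxcl1 stood at 9277 CPM in mesothelial cells, 5922 CPM in pericytes and 5347 CPM in fibroblasts, and the monocyte attractant gene Ccl2 at 5022 CPM in fibroblasts, 3895 CPM in mesothelial cells and 3669 CPM in Schwann or glial cells. Blood endothelial cells had Csf3 at 991 CPM and Il6 at 867 CPM. Cd74, the MHC class II chaperone, was at 52120 CPM in Langerhans cells, which were named in part by it, and 16169 CPM in B or plasma cells.

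YFP UMIs were also set beside HH readouts cell by cell. The 16 cells of YFP-poor clusters with a YFP UMI had Ptch1 at 149 (115 to 190) CPM, Gli1 at 32.6 (17.8 to 54.7) CPM, Krt17 at 3627 CPM and Ces1f at 349 CPM, against 8.6, 1.6, 221 and 9.5 CPM in the 1892 without. Among YFP-bearing basal cells, the 107 with a YFP UMI had Ptch1 at 465 (432 to 500) CPM and the 200 without at 550 (522 to 579) CPM. Their Epcam levels were 739 and 598 CPM.

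The matrix or secreted protein genes Fbln2, Tnc, Wif1, Fbln1, Fndc1 and Igfbp5, chosen after their values were seen, stood higher in YFP-bearing than in YFP-poor basal cells, for example Fbln1 at 236.9 against 36.1 CPM and Igfbp5 at 117.7 against 12.6 CPM. RNA of fibroblasts would need a share of 15.1% to give the Fbln2 level, and the summed level of 6 fibroblast markers was 68.8 CPM, 2.2% (1.95 to 2.47) of the 3124 CPM needed, with Col1a1 at 2.1 CPM and Dcn at 54.2 against 39.3 CPM. Wif1 stood at 0.8 CPM in fibroblasts and at 149.9 CPM in YFP-bearing basal cells. The 10 cells with most UMIs of the 6 genes held 9.7% (8.8 to 10.7) of them, and 302 of the 307 cells had at least 1, so a few cells do not hold the signal. Expression by the YFP-bearing basal cells themselves remains a hypothesis, and no biological explanation was tested.

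Ptch1 and Gli1 were lower in YFP-bearing suprabasal than in YFP-bearing basal cells. YFP-poor cells mixed into the suprabasal cluster would lack YFP UMIs, but among cells with a YFP UMI the Ptch1 log2 ratio was -1.36 (-1.57 to -1.15), against -1.40 in all cells. Without the 100 most abundant genes in the totals the Ptch1 log2 ratio was -1.45, and after subtraction of the empty-droplet profile it was -1.40. The 100 genes held 42.7% of UMIs in suprabasal and 43.9% in basal cells, and the subtraction took 1.76% and 1.58%. Neither these genes nor free RNA therefore accounted for the lower share. Median depth was 27433 UMIs in suprabasal and 13099 in basal cells. Among cells with a YFP UMI, Ptch1 had 255 UMIs in 44 suprabasal cells and 736 UMIs in 107 basal cells. Per cell these counts lie closer together than the shares of UMIs do, so much of the lower share goes with the greater depth. Whether that depth reflects more total RNA per suprabasal cell was not tested. A lower response to the pathway above the basal layer is a hypothesis that the lower share alone cannot carry, and no biological explanation was tested.

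Of the 307 YFP-bearing basal cells, 4 (1.3%, 0.36 to 3.3) had at least 3 UMIs of at least 2 of 4 simple keratins (Krt7, Krt8, Krt18 and Krt19), against 0 of 740 YFP-poor basal cells, a rule set after these cells were seen. Over their 48122 UMIs they had Krt8 at 2805 CPM, Krt18 at 3554 CPM, Krt7 at 1808 CPM, Krt19 at 2639 CPM, Krt20 at 956 CPM and Epcam at 2369 CPM, with 6 Ptch1, 2 YFP and 0 Gli1 UMIs. Of basal genes, Krt14 had 3 UMIs (62.3 CPM, against 4638 CPM in YFP-poor basal cells), and the 19 Krt5 and 2 Trp63 UMIs each lay in 1 of the 4 cells. These 4 cells held 135 of the 138 Krt8 UMIs and 171 of the 199 Krt18 UMIs of the YFP-bearing basal cells. Mesothelial markers had 0 UMIs, with an exact Poisson upper bound of 76.7 CPM, 6.9% of the level in mesothelial cells. Krt8 in empty droplets was 0.11% of its level in the 4 cells, and their highest doublet score was 0.032. That these are rare columnar-like cells may be proposed as a hypothesis only, since 4 cells are few and no biological explanation was tested.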
